A study of Lactococcus lactis with 14 samples.

How the data were processed

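Total RNA of 14 pairs of samples was hybridised to tRNA arrays. Per the labels' protocols, equal amounts of 3 tRNA standards (16 nM each) were added to 2 µg total RNA, the tRNAs were deacylated and oligonucleotides carrying Cy3 or Atto635 were ligated to their 3' ends. Per the labels, Cy3 held the culture at 0.15 per h on every chemostat array and Atto635 the other culture, with no dye swap, while replicate 2 of the OpuA arrays had the dyes swapped against replicate 1. The deposited scanner tables give the spot intensity and local background of 1 dye each, as linear values per the file headers. Per the file headers, the GenePix Pro software had version 6.1.0.4 for all chemostat arrays and for replicate 1 of the OpuA experiment, and 7.2.22 for replicate 2, which was read on another scanner model. The Cy3 gain on scan day 2 of the chemostat was 450 at 0.15, 500 at 0.3 and 0.5, and 550 at 0.6 per h, whereas it was 450 on scan day 1. In both experiments a replicate number was also a scan day, so that a block on scan day is the same fit as a block on replicate number.

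A second deposited table, the authors' processed values, holds log2 ratios for the 39 tRNAs. Set against the scanner values, 11 columns ran as Atto635 over Cy3 and 3 as Cy3 over Atto635, with absolute correlations of 0.91 to 0.99. The 3 turned columns are the OpuA arrays of replicate 2. Column medians ran from -0.62 to 1.03, and the constant used for centring stays unknown. These values were used only as an alternative.

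The values were computed with R 4.3.3 and limma 3.58.1. Background was corrected with normexp (offset 50), spots flagged in either dye were left out, the log2 ratio Atto635 over Cy3 was averaged over up to 24 spots of a tRNA, and the median of the 3 standards was subtracted. Probes Leu6UAA2 and Leu6UAA3 were joined as Leu6UAA, as in the authors' table. A tRNA counts as above blank on an array if its median signal exceeds the 95% quantile of the water spots. The unit of change is the log2 ratio of tRNA per total RNA against the standards, and because the median of all tRNAs differs from 0 by over 0.1, relative changes centred on that median are among the alternatives. The median estimate over all 39 tRNAs was 0.24, 0.14 and 0.15 at 0.3, 0.5 and 0.6 against 0.15 per h, -0.10 at 0.6 against 0.3 per h, -0.34 after induction and 0.16 in stationary phase.

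Each experiment was fitted apart with limma, with a dye term per tRNA that the self-against-self arrays and the swapped arrays estimate, and Benjamini-Hochberg adjustment over 39 tRNAs at 0.05. Lists fixed by amino acid and first anticodon base were tested with camera (preset correlation 0.01) over 9 lists of at least 3 members, with fry, which tests a list against no change, beside it. Lists by gene copy number, codon usage or position near rRNA genes were not analysed here, because they need a genome with tRNA names. The general tRNA level over growth rate was tested by exact permutation; the arrays of the OpuA experiment are not exchangeable, so their levels are given with the SE of a linear model on the array medians, chosen after seeing the data. The groups have 2 arrays, so that no outlier test applies. Named tRNAs were chosen by a rule fixed before the data were examined: those past the threshold, the 5 highest and 5 lowest estimates where fewer than 10 passed, the extremes of each list, the tRNAs of lysine, arginine, leucine and methionine, and the 3 standards. Which methionine probe is the initiator is not given in the sources used here.

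On simulated data with the spread of the real arrays and 8 of 39 tRNAs changed, a change of 1 on the log2 scale was recovered for 40.2% of them at 0.6 against 0.15 per h and for 63.2% after induction, and a change of 2 for 94.5% and 100%. For stationary phase against after induction, the figures were 22% and 97.5%. For a trend, a change of 1 over the whole range of rates was recovered in 58.8%. The simulated noise was independent for each tRNA and array. Deviations shared by a scan day, noise of the standards and signal near background were not simulated, so these figures may overstate recovery.

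Arrays of the chemostat with the same replicate number deviated together from their group means, with correlations across tRNAs of 0.19 to 0.82 over the 6 pairs of groups. In the OpuA experiment those correlations were -0.32, 0.09 and 0.29. The 0.15 per h self-against-self array of replicate 2 correlated across tRNAs with r = -0.57 with the array at 0.6 per h of replicate 1; the dyes of these arrays are given by the labels, and the direction was kept. None of the 91 pairs of arrays shared a spot with identical values in both dyes.

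Alternatives covered background correction, centring, loess, each standard left out, the median of spots, a filter on dim tRNAs, the dye term, a joint fit, the variance model, the replicate block, each array left out and the authors' values. Spots flagged as not found kept, an offset of 0, and loess or the all-tRNA median together with the block were added after seeing the data.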

Results

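The abundance of the tRNAs of Lactococcus lactis, a lactic acid bacterium used in cheese making, was measured on 14 tRNA microarrays of 2 colours. The arrays belong to 2 experiments that differed in strain, medium and culture. The array carried probes for 39 tRNAs of this species, named by amino acid and anticodon, so that Arg4UCU stands for a tRNA of arginine with the anticodon UCU. In the first experiment, glucose-limited chemostat cultures were held at growth rates of 0.15, 0.3, 0.5 and 0.6 per h, and every culture was set against the culture at 0.15 per h, including that culture against itself. In the second experiment, cells carried a plasmid with opuA, a gene of an osmoregulatory transporter, behind a promoter switched on by the peptide nisin. Cells before induction were set against themselves, against cells after 1 h of induction with 0.005% nisin A at an optical density of 1.5, and against cells in stationary phase after induction. Each of the 7 groups had 2 arrays, described in the labels as biological replicates. The number of arrays limits the precision of every value below.

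Each array had 1200 spots, of which 997 to 1168 were used. The median tRNA signal over local background ran from 523 to 2368.5 in Atto635 and from 67 to 1193.5 in Cy3, and the dimmest Cy3 channel belonged to the array of replicate 1 that set cells before induction against themselves. No spot exceeded 27359. Of the 39 tRNAs, 32 were above the blank spots in both dyes on all 14 arrays. The other 7 were Arg2CCG, Arg3CCU, Leu2CAG, Met4CAU, Ser1GGA, Ser2CGA and Thr2CGU, of which Met4CAU was above blank in both dyes on 9 arrays, Ser2CGA on 10, Arg3CCU on 10, Arg2CCG on 11, and Leu2CAG, Ser1GGA and Thr2CGU on 13. Ratios were centred on 3 tRNAs added in equal amounts, EcLys2, EcTyr2 and YeastPhe3. On a single array these standards lay 0.17 to 1.29 apart on the log2 scale, with the widest gap at 0.6 per h in replicate 2, where EcTyr2 stood at 0.96 and YeastPhe3 at -0.32.

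The arrays of a culture against itself show the dye ratio of each tRNA with no difference of culture. Replicate 1 minus replicate 2, their ratios ran from -0.84 (Met4CAU) to 1.82 (TrpCCA) on the log2 scale in the chemostat experiment and from -1.69 (HisGUG) to 1.23 (AsnGUU) in the OpuA experiment.

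**Figure D1:**
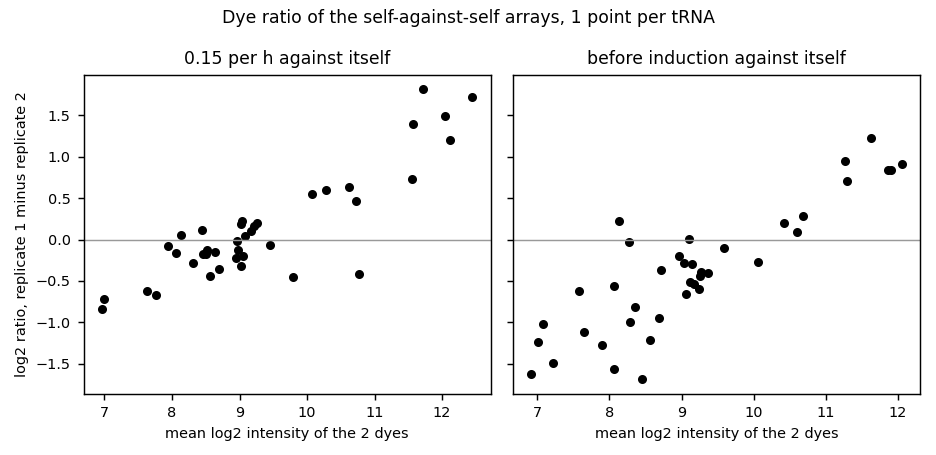
Difference of the log2 dye ratio between replicate 1 and replicate 2 of the self-against-self arrays (y axis) by mean log2 intensity (x axis), with 1 point per tRNA and 39 tRNAs in each experiment. The brightest tRNAs lie above 0 in both experiments, up to 1.82 and 1.23.

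The first question was how tRNA abundance depends on growth rate. The lowest slopes over growth rate belonged to Arg4UCU, Thr2CGU, Leu2CAG, Leu1AAG and Ser5GCU, and the highest to Ser2CGA, Met4CAU, AspGUC, ProUGG and Met3CAU. Arg4UCU, whose anticodon pairs with the arginine codon AGA, had a slope of -1.79 ± 0.48 (SE) on the log2 scale per 1 per h, with -1.45 within scan day 1 and -2.12 within scan day 2. Its mean log2 ratio to the 0.15 per h culture was 0.96 ± 0.25 (SD, n = 2) at 0.15 per h and 0.17 ± 0.05 (SD, n = 2) at 0.6 per h. Thr2CGU had a slope of -1.38 ± 0.59 and Leu2CAG one of -1.20 ± 0.60, each below 0 on both scan days.

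None of the 39 tRNAs passed the test of a trend (limma, adjusted p under 0.05), and 2 had an unadjusted p under 0.05. The smallest adjusted p was 0.15, for Arg4UCU. Without the 2 self-against-self arrays, the smallest limma adjusted p of any tRNA was 0.66. On all 8 chemostat arrays, with the replicate number, which is also the scan day, as a term, 1 tRNA passed. Arg4UCU fell by 1.79 per 1 per h there, with a limma adjusted p of 0.042. The other arginine tRNAs were not called, with slopes of -0.66 ± 0.79 for Arg3CCU, 0.05 ± 0.63 for Arg2CCG and 0.04 ± 0.47 for Arg1ACG. Among the lysine tRNAs, Lys1CUU had a slope of -0.73 ± 0.47, against 0.28 ± 0.51 for Lys2UUU and 0.08 ± 0.53 for Lys3UUU. The leucine tRNAs ran from Leu2CAG up to Leu6UAA at 1.00 ± 0.76, with Leu1AAG at -0.93 ± 0.52, Leu4CAA at 0.10 ± 0.44, Leu3UAG at 0.26 ± 0.44 and Leu5UAA at 0.55 ± 1.30. Of the methionine tRNAs, all with the anticodon CAU and none named as the initiator, the slopes ran from 0.46 ± 0.48 for Met2CAU to 1.28 ± 0.97 for Met4CAU. Ser2CGA had the highest slope, 1.79 ± 0.80, with 3.55 within scan day 1 and 0.03 within scan day 2. Ser2CGA and Met4CAU were each above blank in both dyes on only 6 of the 8 chemostat arrays, so their slopes and ranks partly rest on signal near background.

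**Figure D2:**
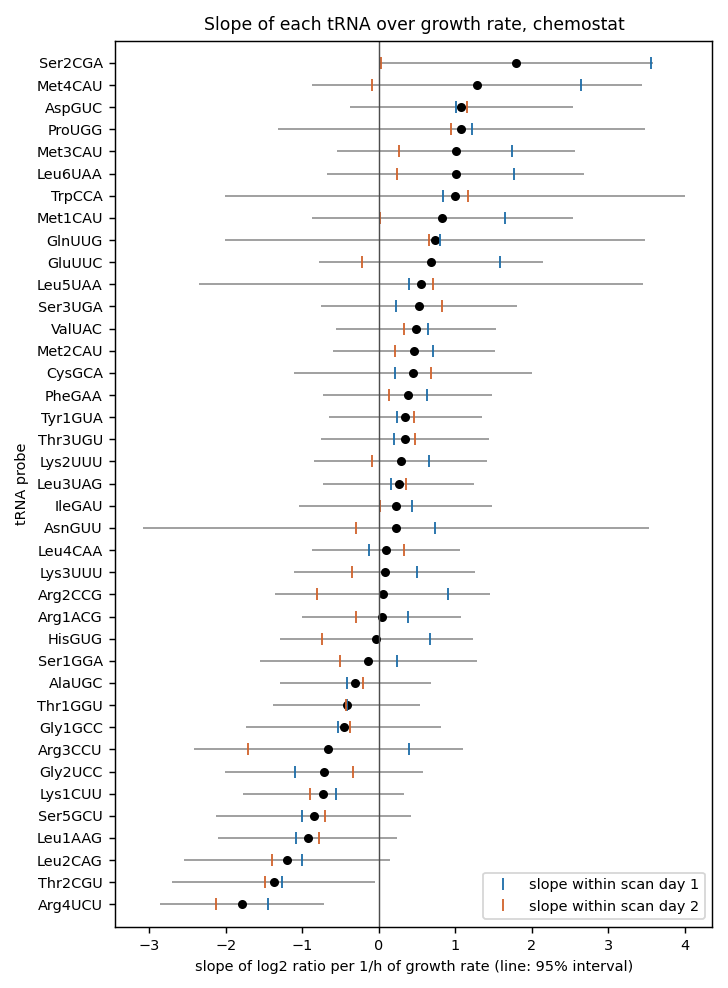
Slope of the log2 ratio of each of the 39 tRNAs over growth rate (x axis, per 1 per h), with points for the fit over 8 arrays, grey lines for the 95% interval and ticks for the slope within each scan day. Arg4UCU lies lowest at -1.79 and Ser2CGA highest at 1.79, and the ticks of Ser2CGA lie far apart.

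**Figure D3:**
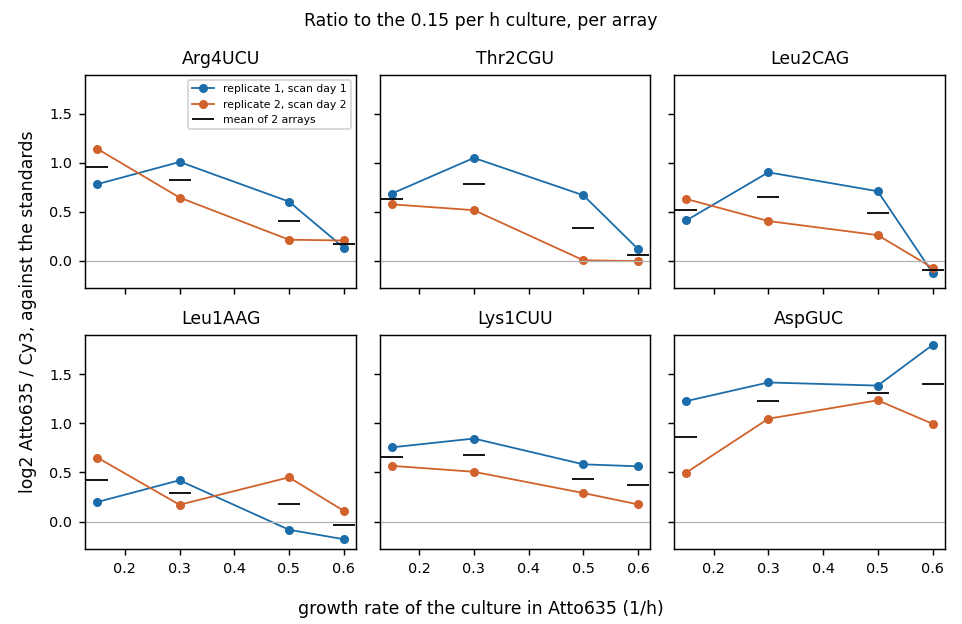
Log2 ratio of 6 tRNAs per array (y axis, Atto635 over Cy3 against the standards) by growth rate (x axis, per h), with coloured lines joining the 4 arrays of a scan day and bars for the mean of 2 arrays. Arg4UCU goes from a mean of 0.96 at 0.15 per h, where the culture is set against itself, to 0.17 at 0.6 per h.

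At 0.6 against 0.15 per h the lowest estimates were those of Arg4UCU, at -0.79 ± 0.27 (SE), Leu2CAG, at -0.62 ± 0.28, Thr2CGU, at -0.57 ± 0.31, Leu1AAG, at -0.46 ± 0.29, and Arg3CCU, at -0.46 ± 0.42. The highest were Ser2CGA, at 0.81 ± 0.45, TrpCCA, at 0.55 ± 0.76, AspGUC, at 0.53 ± 0.37, Leu6UAA, at 0.50 ± 0.42, and ProUGG, at 0.49 ± 0.61. At 0.6 against 0.3 per h the reference cancels, and so does a dye ratio that is constant over arrays. The Cy3 gain on scan day 2 still differed, at 550 for 0.6 and 500 for 0.3 per h. In this comparison Leu2CAG stood at -0.75, Thr2CGU at -0.72, Arg4UCU at -0.65, AsnGUU at -0.48 and Gly2UCC at -0.46. The highest were CysGCA at 0.42, Ser2CGA at 0.32, Met4CAU at 0.24, Ser1GGA at 0.23 and Ser3UGA at 0.23. At 0.5 against 0.15 per h the lowest were Arg4UCU at -0.55, Ser1GGA, Ser5GCU, Thr2CGU and CysGCA, and the highest Ser2CGA at 0.79, Met4CAU, ProUGG, Met3CAU and Leu6UAA. At 0.3 against 0.15 per h the lowest were Ser5GCU at -0.28, Ser1GGA, Arg3CCU, Arg4UCU and Leu1AAG, and the highest AsnGUU at 0.67, TrpCCA, Ser2CGA, Leu6UAA and Thr3UGU.

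Limma called 0 of 39 tRNAs in each of these 4 comparisons, with or without the scan day as a term. At an unadjusted p under 0.05 the counts were 0 at 0.3, 0 at 0.5 and 1 at 0.6 per h against 0.15, and 3 at 0.6 against 0.3; with the scan day as a term they were 1, 4, 5 and 3. The median 95% interval reached 0.72 to either side on the log2 scale. Between scan days, the estimates at 0.6 against 0.15 per h correlated across tRNAs with r = 0.61 and had the same sign for 30 of 39 tRNAs, whereas those at 0.3 against 0.15 correlated with r = -0.36 (tRNAs are not independent replicates).

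The general tRNA level, the median over the 39 tRNAs against the standards, showed no detectable relation to growth rate. This level is tRNA per total RNA and does not measure tRNA per cell. Its mean was 0.51 ± 0.03 (SD, n = 2) at 0.15, 0.71 ± 0.34 at 0.3, 0.60 ± 0.23 at 0.5 and 0.57 ± 0.31 at 0.6 per h. The slope was 0.05 per 1 per h, with Pearson r = 0.042 over 8 arrays (two-sided exact permutation p = 0.93). Spearman rho was -0.15 (exact permutation p = 0.76). These permutations left out the scan day. With the scan day as a block, the permutation p of the slope was 0.92. Without the 2 self-against-self arrays at 0.15 per h, the farthest from the median rate, r was -0.28 and the slope -0.49. Over all rates the slope was 0.37 on scan day 1 and -0.28 on scan day 2. Without 1 array the slope over both days ran from -0.18 (without replicate 1 of 0.6 per h) to 0.37 (without replicate 2 of 0.6 per h), and it was -0.41 without YeastPhe3.

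By amino acid, the 8 tRNAs of the positively charged residues had a median slope of 0.00 and a mean of -0.34, the 2 of the negatively charged residues, AspGUC and GluUUC, had 1.08 and 0.68, and the 4 methionine tRNAs had a median of 0.92. The aromatic list, PheGAA, TrpCCA and Tyr1GUA, had a median of 0.38, the branched-chain list one of 0.24, the small and hydroxyl list one of -0.22, the amide pair AsnGUU and GlnUUG 0.22 and 0.73, and the long variable arm list 0.26. By first anticodon base the medians were 0.41 for U, 0.22 for G and 0.28 for C, and the pair with A, Leu1AAG and Arg1ACG, stood at -0.93 and 0.04. No list passed for the slope (limma camera, smallest adjusted p = 0.32, for the positively charged and methionine lists), and none passed in the 4 comparisons of single rates. For the slope, 1 of the 8 positively charged members, Arg4UCU, passed when adjusted over the list alone and 0 when adjusted over all tRNAs, while the other lists had 0 in either.

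The second question was how overexpression of OpuA and entry into stationary phase alter the tRNAs. Per the labels the cells in stationary phase had been induced too, so that their comparison with cells before induction holds both induction and growth phase. After induction 38 of the 39 estimates against the cells before induction lay below 0, with a median of -0.34, and in stationary phase 33 of 39 lay above 0, with a median of 0.16. The direction after induction depends on the model. With the scan day as a term, 20 of 39 lay below 0, with a median of -0.01. In stationary phase 28 of 39 then lay above 0, with a median of 0.40. Here that term is estimated from the 2 arrays of cells before induction against themselves alone. Their median levels were 0.15 in replicate 1 and 0.53 in replicate 2, so the shift reflects how these dye ratios differ. After induction the lowest estimates were Ser2CGA, at -0.55 ± 0.32 (SE), Met2CAU, at -0.54 ± 0.31, Leu5UAA, at -0.51 ± 0.32, Met1CAU, at -0.51 ± 0.32, and AspGUC, at -0.48 ± 0.32. The highest were Arg4UCU, at 0.01 ± 0.30, Lys1CUU, at -0.00 ± 0.30, Leu1AAG, at -0.01 ± 0.31, Arg2CCG, at -0.08 ± 0.32, and Arg1ACG, at -0.11 ± 0.31. In stationary phase the highest were Lys1CUU, at 0.58 ± 0.30, AsnGUU, at 0.58 ± 0.32, Thr2CGU, at 0.52 ± 0.31, Arg1ACG, at 0.46 ± 0.31, and AlaUGC, at 0.36 ± 0.30, and the lowest were Ser5GCU, at -0.29 ± 0.31, Arg3CCU, at -0.17 ± 0.33, Ser1GGA, at -0.06 ± 0.30, Thr1GGU, at -0.05 ± 0.30, and Met2CAU, at -0.05 ± 0.31. Of the 6 OpuA arrays, Arg3CCU was above blank in both dyes on 2, Ser2CGA and Arg2CCG on 4, and Thr2CGU and Ser1GGA on 5. Their estimates and ranks in this experiment therefore partly rest on signal near background.

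Limma called 0 of 39 tRNAs after induction and 0 in stationary phase, and no tRNA had an unadjusted p under 0.05 in either. With the scan day as a term, which here is also the scanner and the dye orientation, the calls stayed at 0, with 6 and 9 tRNAs at an unadjusted p under 0.05. Single estimates moved with that term. Of the 5 lowest after induction, Ser2CGA went to 0.07, Met2CAU to 0.07 and Met1CAU to 0.13, while Leu5UAA went to -0.94 and AspGUC to -0.90. AsnGUU after induction went from -0.47 to -1.08, with -1.60 within scan day 1 and -0.56 within scan day 2, and AsnGUU in stationary phase went from 0.58 to -0.04, with -0.82 and 0.74. The estimates of the 2 scan days correlated across tRNAs with r = 0.30 after induction and r = -0.11 in stationary phase. The median 95% interval reached 0.62 to either side.

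In the direct comparison against the standards, stationary phase had estimates above the cells after induction for 38 of 39 tRNAs, with a median of 0.49. On both scan days 35 tRNAs lay higher. These counts include a shift shared by the tRNAs. Centred on the median of all tRNAs, 24 lay above 0 and 15 below. With that centring 23 tRNAs had the same sign on both scan days, with r = 0.17 across tRNAs. The linear model of array medians with a dye term, chosen after seeing the data, put the level against the standards at 0.46 ± 0.21 (SE). AsnGUU was highest at 1.04 ± 0.46, followed by Leu5UAA at 0.87 ± 0.46, Met1CAU at 0.81 ± 0.45, Ser2CGA at 0.70 ± 0.45 and TrpCCA at 0.67 ± 0.45. Ser5GCU was lowest at -0.05 ± 0.44, then Leu1AAG at 0.15 ± 0.43, Arg3CCU at 0.20 ± 0.46, Arg2CCG at 0.20 ± 0.45 and Ser1GGA at 0.22 ± 0.43. Limma called 0 of 39, with 1 tRNA, AsnGUU, at an unadjusted p under 0.05 and a smallest adjusted p of 0.48. Without replicate 1 of the cells before induction, AsnGUU was called higher, with a limma adjusted p of 0.014.

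**Figure D4:**
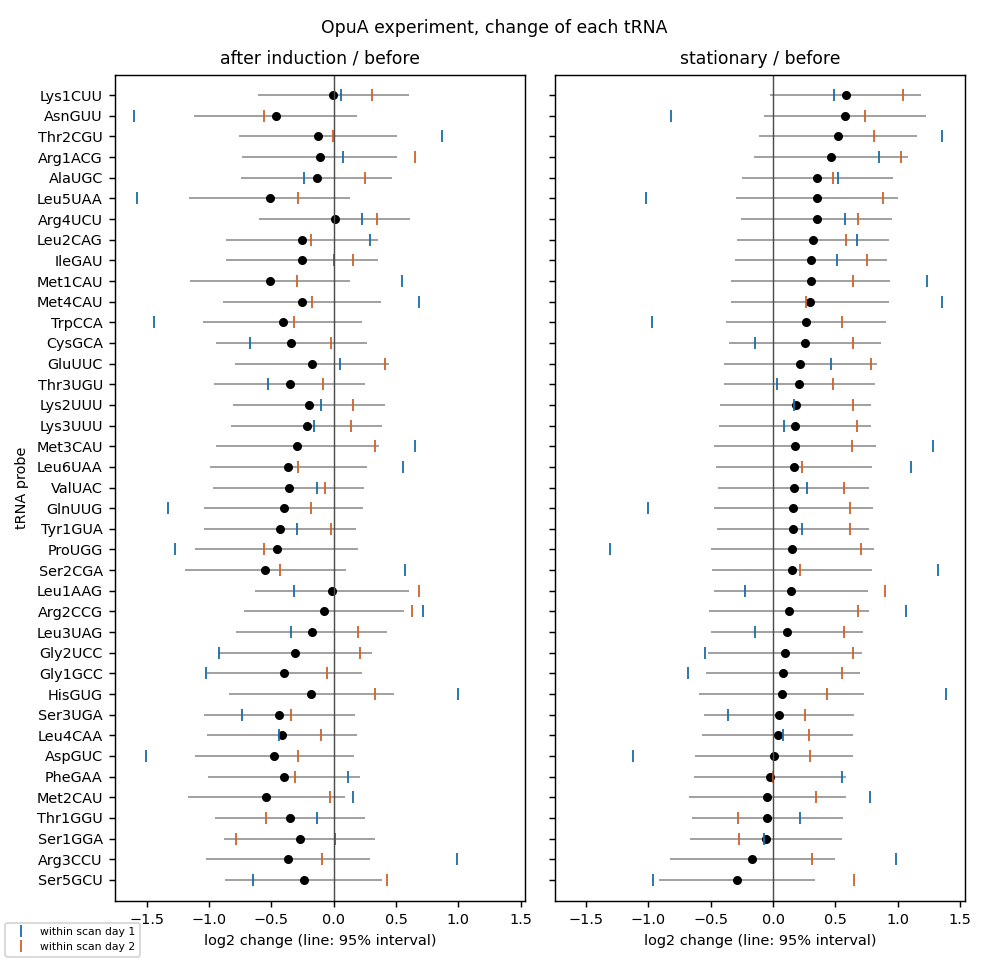
Log2 change of each of the 39 tRNAs (x axis) after induction and in stationary phase against before induction, with points for the fit over 6 arrays, grey lines for the 95% interval and ticks for each scan day. The ticks of AsnGUU after induction lie at -1.60 and -0.56, and in stationary phase at -0.82 and 0.74.

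The median tRNA level against the cells before induction stood at -0.27 ± 0.22 (SD, n = 2) after induction and 0.19 ± 0.15 in stationary phase. On the arrays of the cells before induction against themselves it was 0.34 ± 0.27, which is a dye ratio. A linear model of the array medians with a dye term, chosen after seeing the data, gave the levels after induction and in stationary phase an SE of 0.15 on 3 residual degrees of freedom. With the scan day as a term they were -0.08 ± 0.17 (SE) and 0.38 ± 0.17 on 2 residual degrees of freedom. An exact permutation over the 15 splits of 6 arrays into 3 pairs gave p = 0.13 (smallest possible 0.067). It does not test a change of level, because the arrays are not exchangeable: the self-against-self arrays hold a dye ratio alone, and scan day, scanner and dye orientation are left out.

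With the preset correlation, a single fixed list was called after induction: the 8 tRNAs of the positively charged residues arginine, lysine and histidine had a median of -0.15 against -0.36 for the rest (limma camera, adjusted p = 0.0029 toward higher). Its test points upward although its median is below 0, because it is relative to the other tRNAs. With an estimated correlation the adjusted p was 0.92, and with the scan day as a term 0.014, or 0.63 with an estimated correlation as well. Fry, which tests the list against no change and not against the other tRNAs, gave an adjusted p of 0.63. The call needs both arrays after induction, and was lost without either of them. With the dim tRNAs left out no list was called (smallest limma camera adjusted p of any list 0.27). That filter dropped the arginine tRNAs and Lys1CUU, however, so it does not bear on the call of this list. Those tRNAs had a mean spot intensity under 2 times local background in a dye on some array of either experiment. The members of the positively charged list ran from -0.37 for Arg3CCU to 0.01 for Arg4UCU. Of these, 0 of 8 passed, adjusted over all tRNAs or adjusted over the list alone. Among the OpuA arrays, Arg3CCU was above blank in both dyes on only 2 and Arg2CCG on 4. The range and the call of this list therefore include signal near background. No other list passed in the OpuA experiment without the scan day. With it, the list of anticodons starting with C also passed in stationary phase (limma camera, adjusted p = 0.022, against 0.78 without it, and 0.44 with the scan day and an estimated correlation). The methionine list had medians of -0.40 after induction and 0.23 in stationary phase, the aromatic list -0.41 and 0.16, and the branched-chain list -0.31 and 0.17.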

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

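A probe named Eck gave a signal on every array although the labels do not list it among the added standards. Its median signal over local background was 823.75 in Atto635 and 578 in Cy3, against 1.5 and 10.5 for the water spots, and it was above blank in both dyes on all 14 arrays. The probe is among the controls of the array and no comparison uses it. What it detects is not given in the sources used here, and no explanation was tested.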

How the results depend on the processing

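The settings loess with the block, the all-tRNA median with the block, an offset of 0 and unfiltered flags were chosen after seeing the data; where a count moved, the cause was not tested. The trend over growth rate called 0 tRNAs against the standards, and 1 (Arg4UCU) with local background subtracted, without the standard EcTyr2, with intensity trend and robust variance, with the replicate block, with the authors' processed values and with the median of all tRNAs with replicate block. It called 2 (Arg4UCU and Thr2CGU) centred on the median of all tRNAs or after loess, and 5 after loess with replicate block. The slope of Arg4UCU stayed below 0 in all 25 alternatives that kept it, from -2.68 to -1.05, and was called in 9 of them. The filter on dim tRNAs kept those with a mean spot intensity of at least 2 times local background in both dyes on every array. It dropped Arg4UCU, Thr2CGU and Leu2CAG, which were thus dim on some array, and does not test their slopes. The limma adjusted p of Arg4UCU ran from 0.0010 (loess with replicate block) to 0.99 (without the standard EcLys2). At 0.6 against 0.15 per h, 4 tRNAs were called lower after loess and 11 after loess with replicate block (3 higher, 8 lower), against 0; loess with replicate block also called 2 at 0.5 against 0.15, 9 at 0.6 against 0.3 and 2 in stationary phase against after induction. Loess alone called 3 tRNAs higher in stationary phase. With no dye term 23 tRNAs at 0.3, 7 at 0.5 and 6 at 0.6 per h were called higher, and Arg4UCU at 0.3 turned to 0.83; by construction this setting reads the dye ratio of the self-against-self arrays as a change. The stationary level moved from 0.19 to 0.35 with local background subtracted, to 0.38 with the replicate block and to 0.0060 after loess; it was 0.11 without EcTyr2, 0.32 without EcLys2, without YeastPhe3 or with an offset of 0, and ran from 0.050 to 0.33 without 1 array. The level after induction moved from -0.27 to 0.0082 after loess and to 0.056 after loess with replicate block; loess sets this level near 0 by construction. It was -0.079 with the replicate block and -0.089 without YeastPhe3. Centring on all tRNAs gives no overall level. Of the list tests 1 was called: 0 with camera's estimated correlation, 0 with fry (a test against no change, which does not bear on that call), 2 with the replicate block (also anticodons starting with C in stationary phase) and 3 with the median of all tRNAs with replicate block. Without the dim tRNAs (13 tRNAs kept) 0 were called, but the arginine tRNAs and Lys1CUU were dropped there. That setting therefore does not bear on the call of the positively charged list. Leaving out 1 array at a time gave 0 to 3 list calls (0 without either array after induction, 2 without replicate 2 of the 0.15 per h array, 3 without replicate 2 of stationary phase) and 0 to 1 for stationary phase against after induction (AsnGUU, without replicate 1 of the cells before induction; its limma adjusted p ran from 0.014 to 1 over the alternatives); the lone array left in a group is assumed to vary like the others. The other counts stayed within 1.5 times. The replicate block is the scan day, and it changed no other call.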

Other observations

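The tests on pairs of tRNAs, on stationary phase, on the Cy3 gain and on the self-against-self arrays were chosen after the result was seen. Loess and centring on all tRNAs were planned as alternatives, and were read as tests of an explanation after the result was seen. Within pairs of tRNAs that share an amino acid and the last 2 anticodon bases, the tRNA with C as first base had the lower slope over growth rate in 4 of 6 pairs, among them Thr2CGU against Thr3UGU (-1.38 against 0.34), Leu2CAG against Leu3UAG (-1.20 against 0.26) and Lys1CUU against the 2 UUU tRNAs of lysine (-0.73 against a mean of 0.18). Arg3CCU and Ser2CGA went the other way. A candidate explanation, that the C tRNA falls more than its U partner, was not decided: the mean difference was -0.40 (two-sided exact sign-flip p = 0.47, smallest possible 0.031). Likewise, tRNAs with low slopes may be those that are higher in stationary phase, but the Spearman rho across the 39 tRNAs was -0.0057 (permutation p = 0.97), and -0.17 after loess (p = 0.31); tRNAs are not independent replicates.

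The lower ratio of Arg4UCU at higher growth rates could come from the arrays or from the cells. A dye bias that depends on intensity is argued against, since the slope after loess was -1.78 ± 0.32 (SE) against -1.79 without it. Noise of the standards as the source of the slope is argued against as well, with a slope of -1.84 ± 0.38 when centred on all tRNAs. Whether the slope was called still turned on the standards. The smallest limma adjusted p of the trend was 0.15 with all 3, 0.99 without EcLys2, 0.033 (Arg4UCU, called) without EcTyr2 and 0.12 without YeastPhe3. The Cy3 gain, which was raised with growth rate on scan day 2, cannot be told apart, because the slope on the 4 arrays of scan day 1 alone was -1.45 ± 0.86. Chance cannot be excluded: 5 of 100 rearrangements of the rates within scan days, the real one included, gave a largest absolute moderated t as large as the real 3.72, and the highest other was 4.69, so growth rate itself stays open as a hypothesis. The fit behind these t values held no scan day term, so the call made with that term was not tested in this way.

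The self-against-self arrays held the same group of RNA in both dyes, yet their ratios differed between replicates. TrpCCA lay 1.82 higher in replicate 1 than in replicate 2 of the chemostat experiment, and AsnGUU 1.23 higher in the OpuA experiment. The Spearman rho of this difference with mean intensity across the 39 tRNAs was 0.74 and 0.81, which describes the difference and decides on no cause. Since both dyes held the same group, the difference cannot come from growth rate or induction. No other explanation, technical or biological, was tested for it.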
